A study of Mus musculus with 35 samples.

How the data were processed

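Total RNA of mouse mTECs isolated by FACS was hybridised to Illumina mouse bead arrays as biotin-labelled cRNA made from 200 ng of RNA, per the labels. The labels name 35 arrays, from cells positive and negative for each of 6 antigens. The gates of the sort are not given.

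The deposited unnormalized table holds, per the file headers, a mean bead intensity for 46089 probes and a detection p-value beside each. The lowest intensities were 65.2 to 84.0 per array and none was negative, so these deposited values were not background-subtracted. The deposited series table holds intensities that the authors normalized on a linear scale by a method the files do not state. Image and summarisation software are not stated either. In the unnormalized table, the column labelled as the intensity of Ins2-negative replicate 2 held the detection p-values of Ins2-positive replicate 1, identical for all 46089 probes. That array has no usable unnormalized signal and was left out, so 34 of the 35 planned arrays were fitted.

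The unnormalized table names probes by bead numbers and the series table by the platform's probe identifiers, and no file pairs them. They were linked by matching each probe's values over the 34 arrays in both tables. A link was kept where each was the other's nearest and the nearest distance was under 0.7 of the next. This linked 46054 probes and left 35 out, with a median distance ratio of 0.0733. The link was checked on the array left out. Its series values ranked against its own detection p-values, taken with reversed sign, with a Spearman correlation of 0.989. The same correlation was 0.986 to 0.993 for the other arrays, and -0.00306 for the array left out with shuffled links. Per array, the log2 values of both tables correlated at 0.992 to 1.00 (Pearson). The platform annotation gave 1 symbol to 35667 probes, several to 0 and none to 10422. Symbols were updated with the names of assembly GRCm38.p6, by gene identifier for 28519 probes and by accession for 2634. The platform's own symbol was kept for 4514, and 937 symbols changed. That assembly served only for names and for the order of genes, and no coordinates were used.

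Signals were background-corrected, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. A probe counted as detected at a detection p under 0.05. Probes detected on at least 2 arrays of 1 group were kept (34050). Each gene was represented by its kept probe with the highest mean, which gave 18077 genes. Of 931 called pairs of a named gene and a sort, 385 had another kept probe, and in 336 of these all other probes had the same sign. Detected probes ran from 21715 (47.1%) on Gp2-positive replicate 2 to 28002 (60.8%) on Gp2-negative replicate 1, and median signals from 85.7 to 126.6. Replicates correlated at 0.978 to 0.993 (Pearson, log2 values), with a standard deviation of their differences of 0.254 to 0.480. The number of arrays limits the precision.

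Group means of the 12 groups were fitted with lmFit and eBayes with a mean-variance trend (22 residual degrees of freedom). Each sort's difference, positive minus negative, was tested with limma and adjusted by Benjamini and Hochberg over the genes of that sort, with a threshold of 0.05. The F test of limma was used for differences between sorts. The 38 gene lists were fixed beforehand and tested where at least 3 members were measured, with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 228 list tests were adjusted together. Camera compares a list with all other genes, whereas fry asks whether its own genes move 1 way on balance. Shared calls between sorts were tested with one-sided Fisher's exact tests on the genes tested, and no control arrays were shared between sorts. Neighbourhood was tested by shuffling the called genes over the gene order 10000 times, with the 5 nearest tested genes on either side, in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. The 6 neighbour tests were adjusted together.

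The named genes follow a rule set before the data were examined, as were the design, the gene lists and all alternatives except the 3 named in the closing section. They are the 6 antigens' genes; in each sort the 7 largest increases and 5 largest decreases among called genes whose arrays did not overlap, detected in both groups, plus 3 and 2 detected in only 1 group; Aire, Fezf2, Cd80, H2-Aa and Ccl21a; and up to 4 members per list with the smallest adjusted p. Across sorts, they are the 10 genes called alike in the most sorts and the members of the 5 longest runs of neighbours. Unnamed probes and provisional gene names were left out of the largest changes.

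Alternatives were no background correction, median scaling, normalization within each sort, the authors' normalized values, no detection filter, a stricter one, array weights, every probe on its own, a 2-fold threshold, each sort fitted alone, the replicate number as a block, leaving out each array, 2 or 10 nearest genes, and paralog runs as 1 gene. A paralog run was a row of adjacent tested genes whose symbols were alike up to their first number. The numbering of replicates was checked for pairing by correlating same-numbered arrays' deviations from their group means over genes. All 3 Pdpn correlations were over 0.1 (0.156 to 0.205), so those numbers pair positive and negative arrays by the data alone, as the labels do not say what a number stands for. The other sorts had at least 1 pair under that bound or only 2 pairs.

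The fit was tested on simulated data with 200 genes changed per sort among 18077. The changed genes were drawn only from those detected on most arrays, and values were simulated on the normalized log2 scale. The recovery thus does not cover dim genes or the normalization itself. Over the 6 sorts, the fit recovered 16.4% to 35.8% of genes changed 1.5-fold, 73.1% to 94.0% at 2-fold and 98.5% to 100% at 4-fold, with 5 to 11 unchanged genes called. A planted list was found and 0 of the 227 other list tests were called. The simulated genes varied independently of each other, so this list result does not cover correlation among the members of a list.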

Results

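Gene expression was measured on Illumina mouse bead arrays in medullary thymic epithelial cells (mTECs), the thymus cells that transcribe genes otherwise restricted to peripheral tissues and present their products to developing T cells. Such products are called tissue-restricted antigens. Cells were sorted into fractions positive and negative for each of 6 antigens, by antibody for Pdpn, Gp2, Cea1 and Tspan8 and by reporter mice for Gad1 and Ins2. Cea1 was read as the product of Ceacam1. The 35 arrays formed 12 groups of 3, except for 2 arrays of Gp2-positive cells. Only 34 arrays entered the comparisons, since the unnormalized signal of Ins2-negative replicate 2 was missing, which left 2 Ins2-negative arrays. The labels call the arrays of a group biological replicates without stating whether they came from separate animals. Between 47.1% and 60.8% of the 46089 probes were detected per array, and 18077 named genes were tested. The number of arrays limits the precision of all values. The question of each comparison was which genes are transcribed together with the sorted antigen in mTECs. Differences are positive minus negative cells on the log2 scale with the standard error (SE) of the limma fit.

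The transcript of the sorted antigen rose in the positive cells of all 6 sorts, by very different amounts. Pdpn, a mucin-type membrane glycoprotein, reached a log2 signal of 12.48 ± 0.17 (SD, n = 3) in Pdpn-positive and 8.08 ± 0.30 (n = 3) in Pdpn-negative cells. Gp2, a membrane protein of zymogen granules and microfold cells, reached 14.80 in both Gp2-positive arrays against 10.82 ± 0.18 (n = 3). The probe was the second brightest of its array in both cases, so quantile normalization gave it the same value near the top of the scale, and the spread between Gp2-positive arrays behind the 15.8-fold difference cannot be read from them. Ceacam1, an adhesion molecule, was 27.5-fold higher in Cea1-positive cells (95% interval 19.5 to 38.7; 3 arrays against 3). Tspan8, a tetraspanin, was 27.7-fold higher in Tspan8-positive cells (20.6 to 37.4; 3 against 3). Ins2, an insulin gene, was 3.35-fold higher in Ins2-reporter-positive cells (2.52 to 4.43; 3 against 2). Gad1, an enzyme that makes the transmitter GABA, was 1.58-fold higher in Gad1-reporter-positive cells (1.17 to 2.14; 3 against 3; adjusted p = 0.013). That call was lost without Gad1-negative replicate 3 (log2 difference 0.53, adjusted p = 0.087) and without Gad1-positive replicate 3 (0.50, adjusted p = 0.099). Gad1 signal was 8.17 in Gad1-positive cells. It was higher in the negative cells of the Gp2 (8.89), Cea1 (8.79), Pdpn (8.39) and Tspan8 (8.26) sorts, and lower in all other groups. Ins2 signal was 8.16 in Ins2-positive cells. It was higher in Gad1-positive (9.08), Cea1-positive (8.46) and Pdpn-negative cells (8.43), and lower in all other groups. These levels compare across sorts, which also differed in the antibody or reporter mice used. Only differences within a sort are free of such differences between sorts. Gp2 transcript rose in every sort, by 3.68 in Cea1-positive and 2.88 in Tspan8-positive cells, 2.46 with Gad1, 1.86 with Ins2 and 0.64 with Pdpn. Ins2 transcript rose more in Gad1-positive cells (2.87, SE 0.18) than in Ins2-positive cells (1.74, SE 0.20), and the difference of 1.13 was itself significant (SE 0.27, adjusted p = 0.0026).

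**Figure D1:**
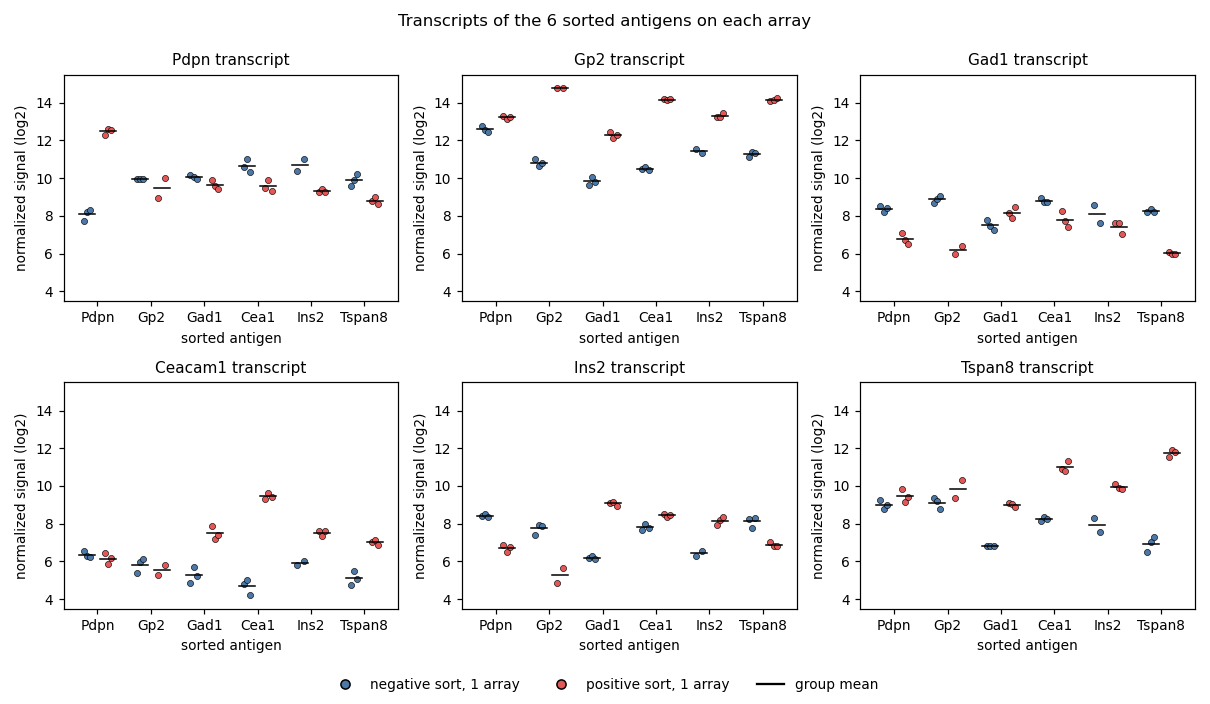
Log2 normalized signal of the transcripts of the 6 sorted antigens on each array, for negative (blue) and positive (red) cells of every sort, with lines at the group means. Each antigen's transcript was higher in the positive cells of its own sort, from a mean difference of 0.66 for Gad1 to 4.79 for Tspan8.

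The Pdpn-positive fraction carried more transcript of basal epithelial, fibroblast and interferon-induced genes and less of many genes of glands and endocrine organs. Its RNA does not show whether the fibroblast transcripts came from the epithelial cells or from fibroblasts carried along. Prelp, a matrix proteoglycan, rose 25.5-fold (log2 difference 4.67, SE 0.25, 3 arrays against 3), Igfbp7 20.8-fold, Scarf2 18.6-fold, the water channel Aqp5 17.7-fold and the matrix Gla protein Mgp 17.2-fold. Pth, the parathyroid hormone gene, was 27.3-fold lower (log2 difference -4.77, SE 0.57, adjusted p = 2.7e-08), and the immunoglobulin light chain segment Igkv1-110 was 28.8-fold lower (-4.85, SE 0.85). Of 18077 genes, 3287 were higher and 3452 lower at an adjusted p under 0.05. A fold is written as at least a value where a gene was detected on no array of the dimmer group. It sets the mean of the brighter group against, per array, the higher of the lowest normalized signal among detected probes and the probe's own signal. The platelet-derived growth factor receptor Pdgfra was at least 8.23-fold higher and the sodium channel Scn1a at least 9.99-fold higher.

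Of the fixed list of CCL21-type and basal mTEC genes, 8 of 9 rose (9 when adjusted over the list alone), with a median of 1.88 (camera adjusted p = 5.4e-09). Krt5, a basal keratin, rose 6.65-fold, the epithelial transcription factor Trp63 3.67-fold and Ccl21a, a chemokine that attracts thymocytes to the medulla, 4.05-fold. Fibroblast and pericyte genes moved with them, with 8 of 10 higher (8 adjusted over the list alone) and a median of 2.26, or 2.22 with undetected members at their bound (camera adjusted p = 1.9e-08). The matrix genes Dcn and Fbln1 rose 7.02-fold and 8.24-fold, and the collagen Col3a1 at least 5.61-fold. Interferon response genes rose for 9 of 13 (10 adjusted over the list alone) with a median of 0.94 (camera adjusted p = 6.4e-05), among them Ifit3 (8.12-fold) and Oas2 (8.71-fold). Immediate early and heat shock genes, which dissociation and sorting can induce, rose for 10 of 12 (11 adjusted over the list alone). Their median was 0.91 (camera adjusted p = 4.6e-06, but adjusted p = 0.064 with an estimated correlation).

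Genes of several glands fell in Pdpn-positive cells. In the kallikrein family, serine proteases largely of salivary gland, 19 of 25 fell and none rose, with the same 19 adjusted over the list alone and a median of -2.02 (camera adjusted p = 1.8e-12). Klk1b8 was 5.39-fold lower. Salivary and lacrimal genes fell for 10 of 13 (11 adjusted over the list alone; median -1.78, camera adjusted p = 2.1e-07). Endocrine genes fell for 12 of 15 under both adjustments (median -1.25, camera adjusted p = 5.6e-06), with the granule protein gene Chga 5.69-fold and glucagon (Gcg) 3.75-fold lower. Exocrine pancreas genes fell for 11 of 15 (12 adjusted over the list alone; median -0.99), with colipase (Clps) 5.48-fold lower. Aire, a transcriptional regulator of tissue-restricted genes in mTECs, was 2.49-fold lower (SE 0.15, adjusted p = 8.9e-09). Fezf2, another such regulator, was 1.87-fold lower, and the costimulatory ligand Cd80, a marker of mature mTECs, 2.72-fold lower. Tuft cell genes fell for 12 of 15 (13 adjusted over the list alone; median -1.21, camera adjusted p = 1.7e-06, but adjusted p = 0.12 with an estimated correlation). The lists of thymocytes, endothelium, and dendritic cells and macrophages were not called in this sort, with medians of 0.06, -0.03 and 0.08. Probes of close paralogs, as in the kallikrein family, can bind each other's transcripts, so that members of a family are not independent measurements.

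Gp2-positive cells carried far more transcript of cortical epithelial and thymocyte genes than Gp2-negative cells. Prss16, a thymus-specific serine protease of cortical epithelium, rose 66.6-fold (log2 difference 6.06, SE 0.29, 2 arrays against 3, adjusted p = 2.4e-17). The chemokine Cxcl12 rose 39.4-fold (5.30, SE 0.21) and Rag1, a recombinase of developing lymphocytes, 30.3-fold (4.92, SE 0.36). The hormone gene Sst was 22.5-fold lower (SE 0.39) and the chemokines Ccl19 and Ccl17 were 17.9-fold and 17.6-fold lower. Cst10, a cystatin, was at least 10.8-fold lower. There were 3241 genes higher and 3793 lower, a share of 46.1% higher. With median scaling in place of quantile normalization, 1605 were higher and 5657 lower (22.1% higher), the median over all genes moved to -0.23, and 4852 genes were called in the same direction by both.

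All 9 genes of the cortical epithelial list rose in Gp2-positive cells, also when adjusted over the list alone (median 2.33, camera adjusted p = 2.0e-10). Ctsl, a protease needed for class II presentation in the cortex, rose 19.4-fold, and Psmb11, the cortical proteasome subunit, 12.3-fold. All 13 thymocyte genes rose too, also when adjusted over the list alone (median 3.21, camera adjusted p = 4.1e-13). Among them, the transcription factor Bcl11b rose 13.7-fold, the signalling protein Themis 9.70-fold and the coreceptor Cd4 7.38-fold. Of 10 microfold cell genes, a list that includes Gp2 itself, 7 rose and 1 fell under both adjustments (median 2.29, camera adjusted p = 4.3e-07). The chemokines Ccl20 and Ccl9 rose 10.1-fold and 4.69-fold, and Tnfaip2 5.13-fold. Proliferation genes rose for 10 of 15 (12 adjusted over the list alone; median 1.10, camera adjusted p = 2.0e-05, but adjusted p = 0.15 with an estimated correlation).

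Genes of mature mTECs and of tissue-restricted programmes fell in the Gp2-positive fraction. RNA of a sorted fraction does not show whether these falls and the rises above occurred in the same cells. MHC class II presentation genes fell for 10 of 11 (11 adjusted over the list alone; median -1.24, camera adjusted p = 2.3e-08), among them H2-Ob (6.39-fold lower) and the class II transactivator Ciita (2.37-fold lower). The mTEC maturation list fell for 10 of 13 with 1 gene higher, under both adjustments (median -1.22, camera adjusted p = 7.0e-06). Aire was 4.80-fold, Fezf2 3.80-fold and Cd80 5.84-fold lower. Of the endocrine list, 12 of 15 fell under both adjustments (median -1.87, camera adjusted p = 4.1e-07), with Gcg 12.2-fold and the neuroendocrine regulator Insm1 10.2-fold lower. Kallikreins fell for 19 of 25 (20 adjusted over the list alone; median -2.37, or -2.29 with undetected members at their bound), and Klk1b1 was 14.3-fold lower. Salivary and lacrimal genes fell for 11 of 13 and skeletal muscle genes for 12 of 15, under both adjustments, with medians of -2.37 and -1.62 (camera adjusted p = 4.0e-09 and 7.6e-07).

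Gad1-positive cells carried more transcript of skin, gut, salivary and liver genes and less of proliferation genes. Sh2d6, a tuft cell adaptor, rose 12.1-fold (log2 difference 3.59, SE 0.23, 3 arrays against 3) and the epidermal genes Sprr2d and Calm4 11.8-fold and 11.2-fold. Slurp1, a secreted epidermal protein, was at least 6.27-fold higher. Pbk, a mitotic kinase, was 11.9-fold lower (-3.57, SE 0.22), and the replication factor Pclaf 11.0-fold lower. In all, 3473 genes were higher and 3475 lower. Neither Aire (-0.10, adjusted p = 0.64), Fezf2 (0.17, adjusted p = 0.27) nor Cd80 (0.10, adjusted p = 0.71) passed the test.

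All 20 genes of the cornified keratinocyte list rose in Gad1-positive cells, also when adjusted over the list alone (median 2.33, camera adjusted p = 3.2e-20), with the suprabasal keratin Krt10 9.87-fold and the envelope protein Lor 6.88-fold higher. Tuft cell genes rose for 14 of 15 (median 1.98, camera adjusted p = 4.5e-12) and intestinal genes for 14 of 15 with 1 lower (median 2.00, camera adjusted p = 3.3e-12), the same counts as adjusted over each list alone. The digestive enzyme Sis and the gut peptide Guca2b rose 8.18-fold and 8.17-fold. Kallikreins rose for 21 of 25 and salivary genes for 10 of 13 with 1 lower, under both adjustments (medians 1.68 and 1.89, camera adjusted p = 1.8e-12 and 7.3e-07). Liver genes rose for 10 of 15 with 1 lower, under both adjustments (median 1.32, camera adjusted p = 1.5e-06), among them the apolipoprotein Apoc3 (7.88-fold) and the transport protein Ttr (7.29-fold). Exocrine pancreas genes rose for 10 of 15 (12 higher and 1 lower adjusted over the list alone; median 1.43, camera adjusted p = 5.1e-06). Endocrine genes rose for 11 of 15 with 1 lower under both adjustments, Ins2 among them (median 1.00, camera adjusted p = 0.00019, but adjusted p = 0.10 with an estimated correlation). The neuron list, which holds Gad1, was not called in this sort (3 of 11 higher, 2 lower, median -0.06). Proliferation genes fell for 13 of 15 under both adjustments (median -2.46, camera adjusted p = 1.1e-12), with the cycling markers Mki67 and Plk1 7.89-fold and 7.91-fold lower. The median signal of the list averaged 9.22 ± 0.43 (SD, n = 3) over the arrays of Gad1-negative cells and 7.65 to 8.58 in the other negative groups. These levels, too, compare across sorts.

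Cea1-positive cells carried the transcripts of tuft cells, the chemosensory cells of epithelia, at high levels. The cation channel Trpm5 was at least 72.9-fold higher (log2 difference 6.42, SE 0.23, 3 arrays against 3, adjusted p = 5.8e-21), and the cytokine Il25 at least 17.5-fold. The taste G protein Gnat3 rose 80.5-fold, the leukotriene pathway protein Alox5ap 71.3-fold, the actin-binding protein Avil 46.8-fold and the phospholipase Plcb2 43.9-fold. Ceacam2 rose 34.5-fold, although its probe could bind transcripts of its close paralog Ceacam1. Phgdh, a serine synthesis enzyme, and Pbk were each 5.25-fold lower, and the mitotic kinase Cdk1 was 4.55-fold lower. There were 2419 genes higher and 2826 lower (46.1% higher). With median scaling, 1382 were higher and 2373 lower (36.8% higher), and 3679 genes were called in the same direction by both.

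Of the tuft cell list, 13 of 15 genes rose in Cea1-positive cells, also when adjusted over the list alone, with a median of 4.32 (camera adjusted p = 1.4e-31). The median signal of the list averaged 10.39 ± 0.51 (SD, n = 3) in Cea1-positive and 5.36 ± 0.07 (n = 3) in Cea1-negative cells. Microfold cell genes, Gp2 included, rose for 8 of 10 under both adjustments (median 1.54, camera adjusted p = 7.8e-08). Lung and airway genes rose for 7 of 13 with 1 lower (2 lower adjusted over the list alone; median 0.64, camera adjusted p = 1.8e-05), led by the secretoglobin Scgb3a2 (10.4-fold) and Cyp2f2 (10.1-fold). Endothelial genes rose for 7 of 10 (8 adjusted over the list alone; median 0.72, camera adjusted p = 0.00014), with Emcn 3.39-fold, the receptor Tek 3.28-fold and the junction proteins Cldn5 and Cdh5 3.44-fold and 1.85-fold higher. Among the lists of other cell types, dendritic cell and macrophage genes rose for 5 of 15 under both adjustments (median 0.40, or 0.23 with undetected members at their bound; camera adjusted p = 0.036, but adjusted p = 0.33 with an estimated correlation). The B cell list was not called (2 of 5 higher, 3 adjusted over the list alone; median 0.54, camera adjusted p = 0.072), nor was the thymocyte list. Fibroblast and pericyte genes fell for 5 of 10 under both adjustments (median -0.58, camera adjusted p = 0.019, but adjusted p = 0.21 with an estimated correlation). Cornified keratinocyte genes rose for 15 of 20 with 1 lower under both adjustments (median 1.41, camera adjusted p = 7.1e-12, but adjusted p = 0.054 with an estimated correlation). Proliferation genes fell for 13 of 15 and MHC class II genes for 7 of 11, under both adjustments (medians -1.46 and -0.56, camera adjusted p = 1.2e-10 and 0.00088). Aire was 1.95-fold lower (adjusted p = 5.1e-06). The Ceacam and Psg family, which holds Ceacam1, was not called (4 of 23 higher, 1 lower, median 0.04).

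Ins2-positive cells carried more transcript of skin, gut and airway genes, whereas the endocrine list was not called. The keratin Krt6b rose 17.2-fold (log2 difference 4.10, SE 0.26, 3 arrays against 2), the transport protein Ttr 13.4-fold (SE 0.22), the iron-binding protein Ltf 13.2-fold and the gut peptides Guca2b and Guca2a 10.8-fold and 10.6-fold. Slc7a9, an amino acid transporter of gut and kidney, was at least 7.28-fold higher. Tmsb10, an actin-binding peptide, was 14.4-fold lower and the chromatin protein Hmgb2 13.2-fold lower. There were 3036 genes higher and 3209 lower, a share of 48.6% higher. With median scaling, 1156 were higher and 5717 lower (16.8% higher), the median over all genes moved to -0.25, and 4068 genes were called in the same direction by both.

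Intestinal genes rose for 12 of 15 with 1 lower in Ins2-positive cells, under both adjustments (median 2.27, camera adjusted p = 4.3e-12), among them the antimicrobial lectin Reg3b (10.1-fold) and the apolipoprotein Apoa4 (7.49-fold). Cornified keratinocyte genes rose for 18 of 20 under both adjustments (median 1.76, camera adjusted p = 2.2e-13), with Sbsn 11.9-fold and the envelope precursor Ivl 7.47-fold higher. Lung and airway genes rose for 8 of 13 under both adjustments (median 0.85, camera adjusted p = 6.1e-06), among them the airway protein Bpifa1 (8.79-fold) and the surfactant protein Sftpd (5.86-fold). Tuft cell genes rose for 11 of 15 (12 adjusted over the list alone; median 1.33, camera adjusted p = 7.6e-07, but adjusted p = 0.11 with an estimated correlation). Of the endocrine list, which holds Ins2, 2 of 15 rose and 2 fell (median 0.28, camera adjusted p = 0.55), and the hormone gene Gcg was 2.81-fold lower. Proliferation genes fell for 12 of 15 under both adjustments (median -1.95, camera adjusted p = 4.9e-10), with Cdk1 8.67-fold and the thymidylate synthase Tyms 7.72-fold lower. Aire differed by -0.47 (adjusted p = 0.028), a call lost without Ins2-negative replicate 1 (-0.32, adjusted p = 0.30), without Ins2-positive replicate 1 (-0.43, adjusted p = 0.072) and without Ins2-positive replicate 2 (-0.47, adjusted p = 0.053). The class II gene H2-Aa was higher by 0.51 (adjusted p = 0.0035) but stood at -0.20 with median scaling, and its call was lost without Ins2-negative replicate 1 (0.46, adjusted p = 0.054).

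Tspan8-positive cells carried the transcripts of cornified epithelium and of tuft cells and less of proliferation and class II genes. The epithelial protease Prss27 rose 40.3-fold (log2 difference 5.33, SE 0.24, 3 arrays against 3), the epidermal oxidase Cyp2b19 39.3-fold, the GABA receptor subunit Gabrp 35.8-fold and Krt6b 29.8-fold. The potassium channel Kcnj16 was at least 6.98-fold higher. Tmsb10 was 14.4-fold lower, the opioid precursor Pdyn 14.0-fold lower and the chemokine Ccl1 at least 8.46-fold lower. There were 3457 genes higher and 4308 lower.

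Cornified keratinocyte genes rose for 18 of 20 in Tspan8-positive cells, under both adjustments (median 3.38, camera adjusted p = 4.3e-19). The calcium-binding protein Calm4 rose 24.5-fold, Ivl 21.9-fold and the barrier protein Flg 20.5-fold. Tuft cell genes rose for 14 of 15 under both adjustments (median 2.49, camera adjusted p = 4.8e-12), among them Sh2d6 (16.1-fold) and the kinase Dclk1 (12.8-fold). Lung and airway genes rose for 7 of 13 with 1 lower under both adjustments (median 1.27, camera adjusted p = 1.3e-05), with Cyp2f2 24.6-fold and Bpifa1 10.2-fold higher. Proliferation genes fell for 12 of 15 (13 adjusted over the list alone; median -2.34, camera adjusted p = 3.8e-09), with Cdk1 13.8-fold and Cdc20 10.3-fold lower. MHC class II genes fell for 8 of 11 (9 adjusted over the list alone; median -1.20, camera adjusted p = 4.1e-07), Ciita by 4.36-fold. Aire was 6.77-fold (SE 0.15, adjusted p = 7.1e-17) and Cd80 3.01-fold lower. The maturation list as a whole fell for 8 of 13 with 2 higher under both adjustments (median -0.94, camera adjusted p = 0.0023, but adjusted p = 0.15 with an estimated correlation). Milk protein genes fell for 6 of 8 under both adjustments, while the milk protein Ltf rose 18.5-fold (median -1.88, camera adjusted p = 0.031, but adjusted p = 0.20 with an estimated correlation).

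Over the 38 gene lists and 6 sorts, 64 of 228 tests were called up and 49 down, and 62 of these calls held with an estimated correlation. No called list had a median, mean and test of differing sign, and none turned direction under median scaling or normalization within each sort. Olfactory receptors (424 genes tested), testis genes and the tetraspanin family, which holds Tspan8, were called in no sort. Of the olfactory receptors, 119 (Cea1 sort) to 228 (Gp2 sort) were detected in neither group, and 76 (Gp2 sort) to 186 (Cea1 sort) in both. Their missing call thus rests largely on signal near the background.

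**Figure D2:**
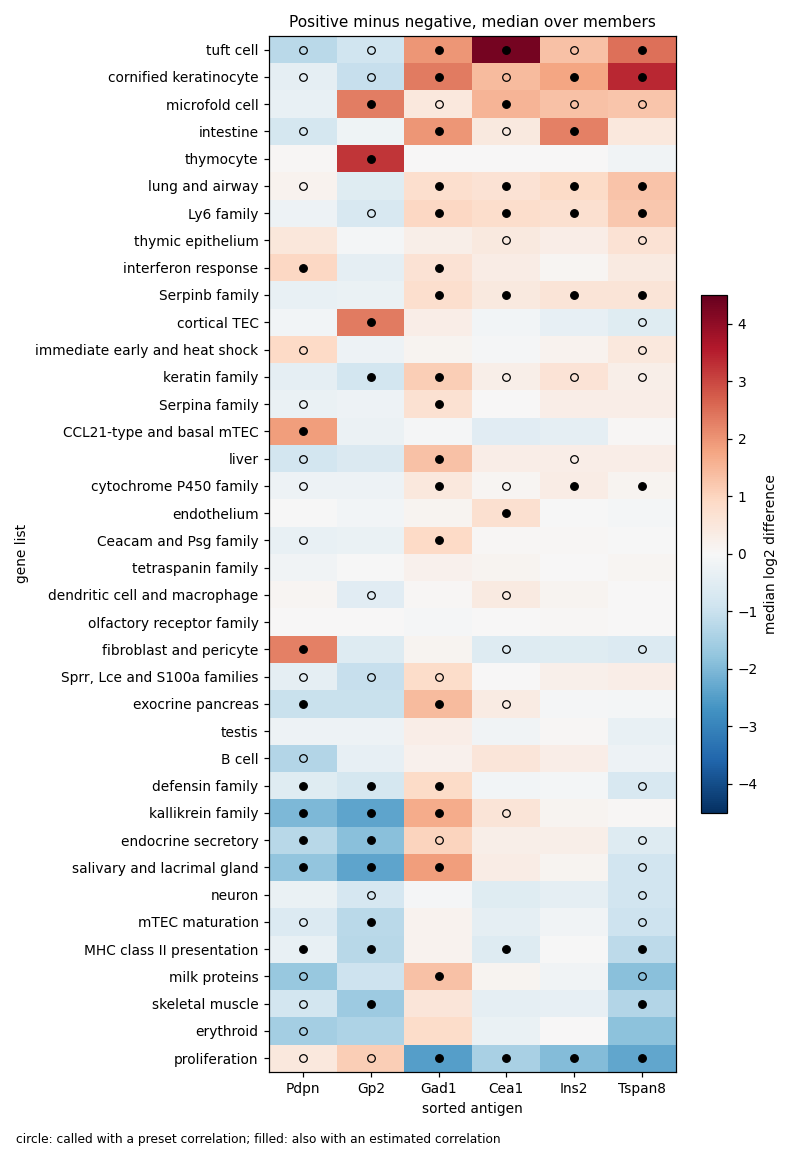
Median log2 difference, positive minus negative, of the 38 fixed gene lists (lines) in the 6 sorts (columns), with open circles for lists called with the preset correlation and filled circles for those also called with an estimated one. Of the 228 cells, 64 carry a circle for higher and 49 for lower genes, and 62 of the circles are filled.

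**Figure D3:**
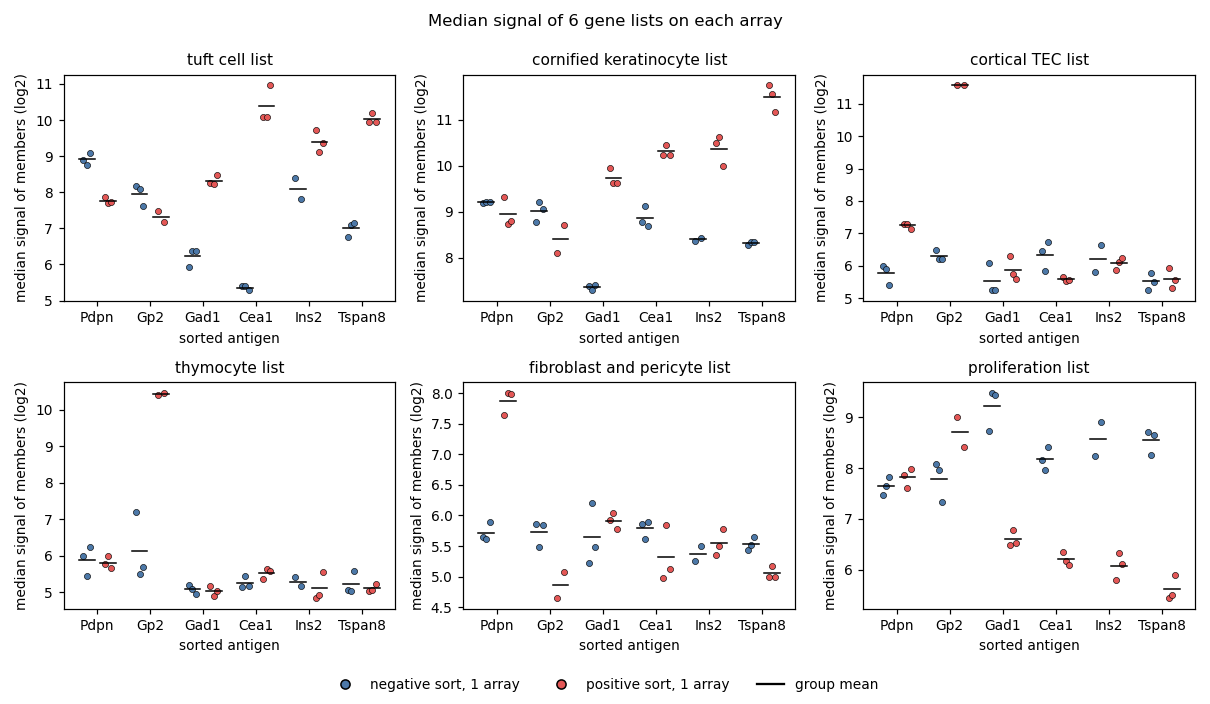
Median log2 signal of 6 gene lists on each array, for negative (blue) and positive (red) cells of every sort. The thymocyte list stood at 10.41 and 10.47 on the Gp2-positive arrays and between 4.84 and 7.19 on all others.

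The sorts differed from each other in 11104 of 18077 genes (61.4%; F test of the 6 differences, adjusted p under 0.05), and some were closely related. Cea1-positive and Tspan8-positive cells shared 1794 higher genes where 462.6 would be shared by independent lists (ratio 3.88) and 2205 lower genes (673.5 by chance, ratio 3.27), and only 69 genes moved in opposite directions. Their log2 differences correlated across genes with a Pearson r of 0.730 and a Spearman rho of 0.677, where genes are not independent replicates. Ins2-positive cells shared 1473 higher genes with Cea1-positive (ratio 3.63) and 1893 with Tspan8-positive cells (ratio 3.26). Pdpn-positive and Gp2-positive cells shared 1408 higher genes (589.3 by chance, ratio 2.39, adjusted p = 7.2e-313, one-sided Fisher's exact test) and 2207 lower genes (ratio 3.05). The other overlaps named so far had Fisher p-values too small to be represented. Fisher's test counts genes as independent, which genes that move together are not. Its p-values thus do not measure the evidence of 2 or 3 arrays per group. Gad1-positive cells went with the Ins2, Cea1 and Tspan8 sorts, with 1621 (ratio 2.78, r = 0.562), 1267 (ratio 2.73, r = 0.477) and 1436 shared higher genes (ratio 2.16, r = 0.346, adjusted p at most 9.1e-261), and stood opposite to the Pdpn and Gp2 sorts. Tspan8-positive cells went with the Pdpn and Gp2 sorts as well, with 1215 higher (ratio 1.93) and 1921 lower genes (ratio 2.34) shared with the Pdpn sort (r = 0.310) and 952 higher (ratio 1.54) and 2084 lower genes (ratio 2.31) shared with the Gp2 sort (r = 0.291; adjusted p at most 1.5e-55). Against the Pdpn sort, Gad1-positive cells shared 479 higher genes (631.5 by chance, ratio 0.759, adjusted p = 1), while 2765 genes moved in opposite directions (1295.1 by chance), and against the Gp2 sort 2663 did (1351.7 by chance). The correlations of the Gad1 sort across genes with the Pdpn and Gp2 sorts were -0.338 and -0.303. These were the lowest of all 15 pairs of sorts. Other cell types carried along in the Pdpn-positive and Gp2-positive fractions stay possible. Their part in the overlaps and correlations of these sorts was not tested.

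A core of 92 genes was higher and 178 genes were lower in all 6 sorts. The genes higher everywhere with the largest mean difference were Ltf (log2 differences 2.27 to 4.37), Prss27 (1.41 to 5.33), Gsto1 (0.98 to 4.72), Krt6b and Gabrp, and Gp2 was also among them. Those lower everywhere included the serine synthesis gene Phgdh (-3.53 to -1.06), the opioid precursor Pdyn (-3.81 to -0.72), the transcription factors Utf1 and Olig1, and Wnt10b.

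**Figure D4:**
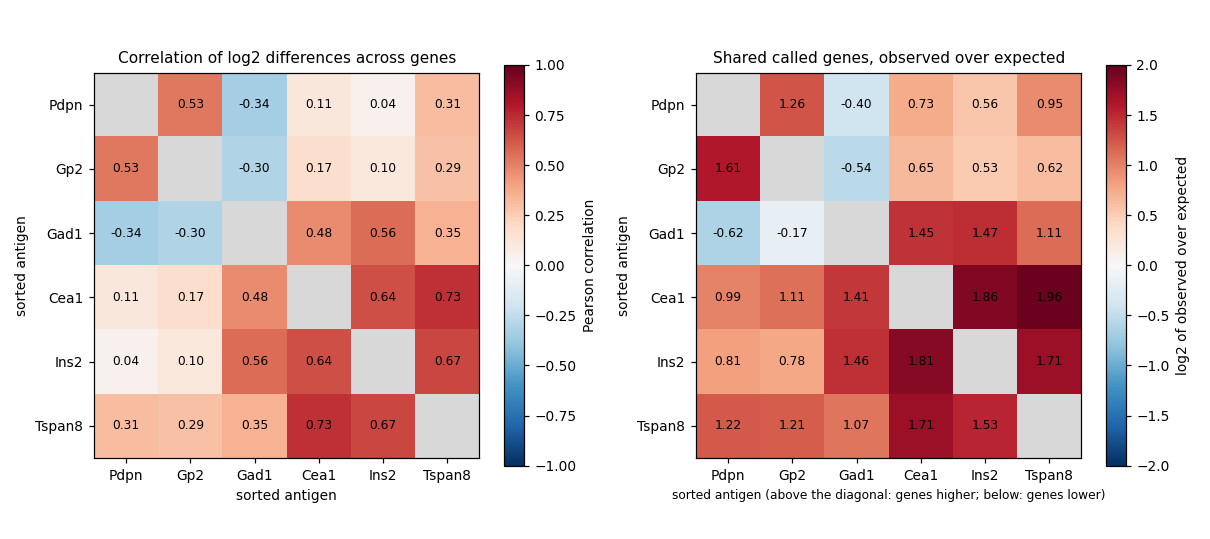
Left, Pearson correlations across genes of the log2 differences between each pair of sorts; right, log2 of the observed over the expected number of shared called genes, with higher genes above and lower genes below the diagonal. Cea1 and Tspan8 form the closest pair (r = 0.730) and Pdpn and Gad1 the most opposed (r = -0.338).

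Whether genes higher in the same sort also lay near each other on the chromosomes was tested on the order of the genes. Among 16163 genes with a known position, higher genes of the Cea1 sort had 1772 with another higher gene among the 5 nearest on either side, against 1727.4 in shuffled orders (ratio 1.03, adjusted p = 0.041, 10000 shuffles). The ratios were 1.01 for Pdpn (adjusted p = 0.049), 1.02 for Gp2 (0.041) and 1.01 for Ins2 (0.049), and for Gad1 (0.996, adjusted p = 0.78) and Tspan8 (1.01, adjusted p = 0.12) the test was not passed. By chance, 2918.3 of 3265 higher genes (Gad1) and 2760.2 of 3129 (Tspan8) had such a neighbour, so the ratios had limited room above 1. With the 2 nearest genes on either side, the ratios were 1.12 for Pdpn, 1.14 for Gp2, 1.12 for Gad1, 1.21 for Cea1, 1.17 for Ins2 and 1.13 for Tspan8 (adjusted p = 0.0001 each, the smallest the shuffles can give). Counting runs of paralogs as 1 gene ended the 4 calls with 5 nearest genes (ratios 1.00 to 1.01, adjusted p from 0.54 to 0.66). With 2 nearest genes, a setting chosen after seeing the data, the ratio was then 1.06 for Pdpn (adjusted p = 0.0003). For the other sorts it was 1.08 to 1.17 (adjusted p = 0.00012 each). Only adjacent genes with symbols alike up to their first number were merged. Paralogs with unlike names stayed separate, so these ratios do not show clustering beyond paralogs. The longest runs of adjacent higher genes were 13 kallikreins from Klk15 to Klk1 in Gad1-positive cells and 11 genes of the Sprr cluster from Sprr2a3 to Sprr1b in Tspan8-positive cells. Tspan8-positive cells also held a run of 8 keratins from Krt2 to Krt18, Gad1-positive cells a run of 8 with the trypsins Try4, Try5 and Try10, and Gp2-positive cells a run of 8 unrelated genes from Xrra1 to C2cd3.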

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

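The tests on further thymocyte and fibroblast genes, on the purity of the Gp2-positive and Pdpn-positive sorts and on genes detected on all Gad1 arrays were chosen after the results were seen.

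Thymocyte transcripts rose with cortical epithelial transcripts in Gp2-positive cells, and thymocytes carried along with the sorted cells are a candidate source. Of 17 further thymocyte genes, none in the fixed list, 94.1% were called higher (median 2.93), with Thy1 at 13.22 against 10.17 and Cd3d at 12.03 against 7.87, although 13 of the 17 and 10 of the 13 fixed genes were also detected on every Gp2-negative array. Weak hybridization of 1 array is argued against, since the thymocyte median was 3.70 without Gp2-positive replicate 2. The medians of 5 lists of other cell types ran from -1.40 to -0.14, so these lists did not rise in general. Members such as Lyz2 (11.35), Acta2 (10.92) and Hba-a1 (9.93) were also bright in Gp2-negative cells. A fall of that signal can hide a contaminant, so the medians cannot decide on a generally less pure sort. The thymocyte list level differed between Gp2-negative arrays as well, with 7.19 on replicate 1 and 5.51 and 5.69 on the others. The cortical genes rose by a median of 2.33 and may mark cortical cells within the gate, which was not tested; the labels give no gate that would exclude thymocytes (CD45) or cortical cells (Ly51).

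Fibroblast transcripts rose with basal epithelial genes in Pdpn-positive cells, and Pdpn is also a surface protein of fibroblasts. Of 19 further fibroblast genes, none in the fixed list, 78.9% were called higher (median 2.25), between the bounds of 50% and 80% set for the test, so carried fibroblasts and transcription by the epithelial cells themselves cannot be told apart for these genes. Among the most abundant fixed genes, Dcn stood at 12.89 against 10.08 and Acta2 at 12.64 against 10.69, while the smooth muscle gene Myh11 was at 8.92 against 8.98. The medians of 5 other lists ran from -1.54 to 0.076, so these lists did not rise in general. Most of their members were detected in both groups, where a fall of their signal can hide a contaminant. The medians thus cannot decide on a generally less pure sort. Of the fixed and further genes, 8 of 10 and 16 of 19 were detected on every Pdpn-negative array, and a gate on CD45-negative, EpCAM-positive cells, which the labels do not state, would remove fibroblasts.

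Tissue-restricted transcripts, Ins2 among them, rose more broadly in Gad1-positive cells than the transcript of Gad1 itself. The Gad1-negative cells had the highest median signal of the proliferation list among the negative groups, 9.22 against 7.65 to 8.58. That goes with a comparison group richer in cycling cells, although levels are compared across sorts. Single arrays overlapped, with 8.73 on Gad1-negative replicate 1 and 8.92 on Ins2-negative replicate 3. In the Tspan8 sort the proliferation list fell by a like median (-2.34, against -2.46 in the Gad1 sort). There the cornified keratinocyte and tuft cell medians were 3.38 and 2.49, but the salivary and lacrimal and milk protein medians -0.86 and -1.88. A fall of this size was thus not joined by a rise of all these lists. Fewer probes were detected on the Gad1-negative arrays. Of the 139 genes of the 10 raised tissue lists, 105 were detected on all 6 arrays. Of these, 93 were called higher and 5 lower (median 1.87, quartiles 1.08 and 2.35), so the rise was not confined to genes undetected on some arrays. The lists were taken because they rose in this sort, so these counts cannot decide whether fewer detected probes are a cause. For the other 34 genes it stays open as well, since detection itself differs there. Which part of the difference belongs to the reporter and which to the cell cycle stays open. Beyond cycling cells in the comparison group, no biological explanation was tested.

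Splits of the 6 arrays of a sort into 3 and 3 are too few (10) for a share under 0.05. The real split was in each case the only 1 of the 10 with as many called genes, with 6739 for Pdpn (highest other 0), 6948 for Gad1 (5), 5245 for Cea1 (10) and 7765 for Tspan8 (0).

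The following lists differed between sorts by a test of the difference itself, given as the median of the differences for the pair with the smallest adjusted p among pairs called in opposite directions, which need not be the pair farthest apart. The first sort lay above the other for cortical TEC genes (Gp2 minus Tspan8, 3.58), proliferation (Gp2 minus Tspan8, 3.81), fibroblast and pericyte (Pdpn minus Tspan8, 2.79), milk proteins (Gad1 minus Tspan8, 3.26) and defensins (Gad1 minus Tspan8, 1.53). It lay below for tuft cell (Pdpn minus Cea1, -5.53), cornified keratinocyte (Gp2 minus Tspan8, -4.04), endocrine (Gp2 minus Gad1, -2.78), intestine (Pdpn minus Ins2, -3.02) and exocrine pancreas genes (Pdpn minus Cea1, -1.40). The same held for liver (Pdpn minus Gad1, -1.95), salivary and lacrimal (Gp2 minus Gad1, -4.33), dendritic cell and macrophage (Gp2 minus Cea1, -1.46), Ceacam and Psg (Pdpn minus Gad1, -1.12) and kallikrein genes (Gp2 minus Cea1, -2.85). It also held for keratins (Gp2 minus Ins2, -1.99), Sprr, Lce and S100a genes (Gp2 minus Gad1, -2.03), Serpina (Pdpn minus Gad1, -1.89), cytochrome P450 (Pdpn minus Ins2, -0.49) and Ly6 genes (Gp2 minus Tspan8, -1.43). Some of the calls behind these pairs were lost with an estimated correlation. Among them were tuft cell genes in the Pdpn sort and proliferation genes in the Gp2 sort. Milk proteins in the Tspan8 sort and dendritic cell and macrophage genes in the Cea1 sort were others. The Ins2 transcript differed by 1.13 between the Gad1 and the Ins2 sort.

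Probes without a gene name, which no comparison used, also carried differences. Of 6433 such probes, 882 were higher in Pdpn-positive, 1139 in Gp2-positive, 563 in Gad1-positive, 539 in Cea1-positive, 673 in Ins2-positive and 857 in Tspan8-positive cells. Lower in the same order were 670, 616, 711, 490, 597 and 708, so that in the Gad1 sort more were lower than higher.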

How the results depend on the processing

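The authors' values without the array lacking a signal, the list calls without each array, and 2 nearest neighbours with paralog runs as 1 gene were chosen after seeing the data. With a threshold of at least 2-fold, by construction fewer genes were called: 1088 higher and 1330 lower for Pdpn, 1176 and 1970 for Gp2, 1514 and 876 for Gad1, 899 and 527 for Cea1, 1195 and 1157 for Ins2, and 1459 and 1821 for Tspan8. Median scaling gave 1605 higher genes for Gp2, 1382 for Cea1 and 1156 for Ins2, and 5717 lower for Ins2. The median of all genes moved to -0.23 and -0.25 in the Gp2 and Ins2 sorts, and the cause of that shift was not tested. All other counts stayed within 1.5 times the reported ones. With an estimated correlation 62 list tests were called, and with fry 177.

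Without 1 array at a time, higher and lower counts ran over 2781 to 3206 and 2936 to 3325 for Pdpn, 2723 to 3040 and 3217 to 3616 for Gp2, 3095 to 3218 and 2944 to 3210 for Gad1, 2087 to 2264 and 2235 to 2569 for Cea1, 2280 to 2888 and 2500 to 3024 for Ins2, and 3031 to 3226 and 3895 to 3981 for Tspan8. The list calls ran over 110 to 124. The antigens' own differences ran over 4.24 to 4.52 for Pdpn, 3.89 to 4.09 for Gp2, 0.50 to 0.81 for Gad1, 4.56 to 4.96 for Ceacam1, 1.62 to 1.87 for Ins2 and 4.57 to 4.98 for Tspan8. The Gad1 call was lost without Gad1-negative replicate 3 (0.53) and Gad1-positive replicate 3 (0.50), which also leaves fewer arrays.

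Neighbour ratios turned under 1 with 10 nearest genes for Pdpn (0.997), Gp2 (0.997), Cea1 (0.993) and Ins2 (0.993), and moved to 0.994 for Tspan8. With 10 nearest genes no sort was called (adjusted p = 0.997 each). By chance alone, 2907.8 of 2963 higher genes of the Pdpn sort and 2117.7 of 2236 of the Cea1 sort had a higher neighbour there. This leaves the ratios almost no room above 1, so this setting cannot decide on clustering. The cause of the turn under 1 was not tested. With paralog runs as 1 gene the neighbour ratios were 1.00 for Pdpn, 1.01 for Gp2, 1.01 for Cea1, 1.00 for Ins2 and 0.997 for Tspan8. With 2 nearest genes all 6 sorts were called, with 1.12 for Pdpn, 1.14 for Gp2, 1.12 for Gad1, 1.21 for Cea1, 1.17 for Ins2 and 1.13 for Tspan8 (adjusted p = 0.0001 each), and with paralog runs as 1 gene as well they were called at 1.06, 1.09, 1.08, 1.17, 1.14 and 1.09 (adjusted p at most 0.0003). Paralogs with unlike names stayed separate in the paralog settings, so the remaining ratios do not show clustering beyond paralogs. The cause of the lost calls with 5 nearest genes was not tested.

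With the replicate number as a block, higher and lower counts were 3512 and 3643 for Pdpn, 3117 and 3699 for Gp2, 3692 and 3710 for Gad1, 2641 and 3101 for Cea1, 3114 and 3223 for Ins2, and 3633 and 4525 for Tspan8. Of 1001 named values the block weakened 9 and strengthened 21, and of 228 list tests it weakened 0 and strengthened 5. In the paired Pdpn sort 6655 of the 6739 called genes kept their call and direction, no named gene or list lost its call, and Smcp, Thy1, Dntt and Tspan8 and the keratin family (median -0.42) were called only with the block. Same-numbered arrays' deviations correlated at 0.106 to 0.229 for Gp2 and 0.0513 to 0.105 for Ins2 (2 pairs each), -0.00164 to 0.0717 for Gad1, 0.0807 to 0.212 for Cea1 and 0.0679 to 0.0852 for Tspan8. Every array correlated best with its own number in the Cea1 and Tspan8 sorts but not in the Gad1 sort.

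Among named genes, direction turned with every probe on its own for Cxcl12 in the Cea1 sort (-0.98) and Smr3a in the Ins2 sort (0.76). It turned with median scaling in the Ins2 sort for H2-Aa (-0.20), Egr1 (-0.22), Oasl2 (-0.20), Krt8 (-0.056) and Cd8b1 (-0.27), and the cause was not tested. Of 1001 named values, 926 kept direction and call with median scaling, 979 with the authors' values and 988 without background correction. Of 5664 values with 1 array left out, 5458 did and 158 lost the call. Many named genes were chosen for large changes or small adjusted p, which favours keeping a call. Over all called genes, median scaling kept call and direction for 4068 of 6245 (Ins2 sort) to 6621 of 7765 (Tspan8 sort). No list call turned direction under any alternative. Olfactory receptors, called in no sort as reported, were called in 5 of the 6 sorts with median scaling. The slide as a block was not run, since the files name no slide. Signal over background limits dim genes: only 47.1% of probes were detected on Gp2-positive replicate 2, and a gene undetected in 1 group has only a bound there.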

Other observations

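Some families not described above rose in 4 of the 6 sorts. Genes of the Ly6 family, small surface and secreted proteins of epithelia and leukocytes, rose for 18 of 25 in Gad1-positive, 14 in Cea1-positive, 14 in Ins2-positive and 15 in Tspan8-positive cells, and fell for 2, 1, 3 and 6 (camera adjusted p = 5.4e-09, 2.4e-07, 0.00043 and 5.1e-05). The medians were 0.92, 0.79, 0.71 and 1.20. In the Gp2 sort the family fell, for 14 of 25 with 3 higher (15 and 3 adjusted over the list alone; median -0.71, camera adjusted p = 0.0022, but adjusted p = 0.065 with an estimated correlation), and in the Pdpn sort it was not called (4 higher, 11 lower, median -0.22). Adjusted over the list alone, 20, 15, 14 and 15 rose and 3, 3, 4 and 8 fell in the 4 sorts. Ly6d was 4.87-fold, 3.30-fold, 4.67-fold and 8.92-fold higher in the Gad1, Cea1, Ins2 and Tspan8 sorts, and Ly6g6c 12.9-fold higher in Tspan8-positive cells. Serpinb genes, intracellular protease inhibitors, rose for 11 of 16 in Gad1-positive and 8 of 16 in Cea1-positive, Ins2-positive and Tspan8-positive cells, and fell for 0, 1, 1 and 2, with medians of 0.77, 0.44, 0.57 and 0.57 (camera adjusted p = 4.6e-06, 0.00077, 0.015 and 0.0093). Adjusted over the list alone, 12, 8, 9 and 8 rose and 0, 1, 2 and 3 fell. In the Gp2 and Pdpn sorts the Serpinb family was not called (medians -0.30 and -0.33). Serpinb11 was 18.3-fold higher with Tspan8 and 8.63-fold higher with Cea1. Both families held with an estimated correlation in these 4 sorts, the highest adjusted p being 0.039 for Ly6 genes in the Ins2 sort.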
